A study of Mus musculus with 2 samples.

How the data were processed

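ChIL-seq for Hnf4a was performed on iHepCs, cells reprogrammed from C57BL/6J mouse embryonic fibroblasts with retroviral Foxa2 and Hnf4a. Per the labels' protocols, 10000 cells were plated per well in collagen-coated plates, cells were fixed with 1% formaldehyde for 5 min, and in situ transcription ran for 20 h; the culture medium held 100 nM dexamethasone and 20 ng/ml each of hepatocyte growth factor and epidermal growth factor. There is 1 group of 2 samples, which the series text calls biological replicates, so no comparison between conditions was possible. The peak names put both libraries in the same numbered lot of cells, so the spread between them may hold less than that between separate reprogramming experiments.

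The submitters' processing notes name fastp 0.23.4, HISAT2 2.0.5, MACS2 2.2.9.1 and build mm10. Each deposited list holds 1-bp peak summits called for each library on its own, with the authors' −log10 q-value per summit. The peak names carry a q threshold of 0.01, and the lowest deposited −log10 q was 2.04 in replicate 1 and 2.01 in replicate 2, just above the 2 that this threshold gives. Whether a control library, removal of duplicates or a filter on problem regions was used is not given in the sources used here. The lists hold no widths, fold enrichments or read counts, so depth per sample is unknown, and intervals on shares of summits cover counting error only. Scores were used only to rank, filter and describe summits. They take few values at the low end: the 5 commonest made up 9.52% of replicate 1 and 15.9% of replicate 2.

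The planned rule that peaks share at least 1 bp would require identical bases for 1-bp summits. Summits within 100 bp, which had been listed as another setting before the data were examined, were therefore taken as shared. Summits of both lists within 100 bp of the next were merged into regions, and a shared region holds a summit of each replicate. The share was set against 1000 random placements of the replicate 2 summits on their own chromosomes, within the span of both lists since chromosome lengths were not used here, and against random shifts of up to 100 kb. The 21 summits of replicate 1 and 24 of replicate 2 on chromosome Y and unplaced or unlocalised scaffolds kept their positions. Intervals on Spearman's rho come from 1000 bootstrap resamples of the regions.

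Gene positions came from the RefSeq gene table of GRCm38.p6, the assembly of mm10, with 21887 protein-coding genes on standard chromosomes used. This table has a start and an end per gene and no strand, so both gene ends stand in for the planned transcription start sites, and the nearest gene stands in for the nearest start site. Location was compared with 10 random positions per summit on chromosomes 1 to 19 and X by two-sided Fisher's exact tests. The 15 gene lists were fixed at the same time, and all 265 entries given by name were matched. Lgr5 is an entry of both the cholangiocyte and the intestinal list. A gene counted as having a region if a region midpoint lay within 10 kb of either end. Lists were compared with all other protein-coding genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 15 lists and a threshold of 0.05, and the replicates were compared by exact McNemar tests. The replicates' scores and lists were not otherwise scaled.

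Named regions followed a rule fixed with the lists. It took the 10 shared regions with the best worse rank of both replicates, the widest 2, the best-scored 2 per replicate without a counterpart, up to 4 members per list in the order of their region's rank, and Hnf4a and Foxa2. Other named genes are marked as chosen after their values were seen, except that all members with a shared region of both lists with higher shares are named. Values of some genes that the rule names are not reported here. The planned test of 15 sequence motifs, including the HNF4 motif, needs the genome sequence and was not run. The share of exon sequence at the genes of the introduced factors, and alternatives that need peak widths, fold enrichment or CpG counts, were not run either.

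The alternatives covered stricter scores (−log10 q of 5 or more), the top 10000 summits, other distances for sharing, other windows around genes, each replicate alone, other backgrounds, covariates for gene length and gene density in a logistic regression, and 1 member per group of neighbouring genes. Scripts were tested on simulated data. With 0%, 20% and 40% of 21262 summits planted as shared, 0.141%, 20.2% and 40.1% were recovered. A list of 28 genes with regions beside 50% of its members was called in 73 of 100 runs over 21887 genes, with 5 false calls among the other lists. These runs drew each gene independently and adjusted over 14 lists, without olfactory receptors. They therefore do not give the power or false call rate of the test on the real lists, where neighbouring genes can share a region. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.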

Results

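Binding of Hnf4a, a nuclear receptor that controls many hepatocyte genes, was mapped by chromatin integration labelling (ChIL-seq), in which a probe on the antibody directs Tn5 transposase to insert a T7 promoter near the bound protein and the tagged DNA is then transcribed in situ. The cells were iHepCs, hepatocyte-like cells obtained from C57BL/6J mouse embryonic fibroblasts by retroviral expression of Foxa2 and Hnf4a. The series text describes 2 biological replicates of this 1 group, and no control samples were analysed here. The deposited lists held 21283 peak summits for replicate 1 and 24097 for replicate 2, or 22690 ± 1990 (SD, n = 2). Each summit is a 1-bp position in mm10 with the authors' −log10 q, which had a median of 7.32 in replicate 1 and 6.67 in replicate 2. Read depth is unknown from these lists. With no control samples analysed and no motif test run, how many of the summits mark Hnf4a binding is unknown too.

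The first comparison asked how far both replicates placed summits at the same sites. Sites beside liver genes were among those found in both. A summit 13149 bp from Alb, which encodes serum albumin, scored 69.5 in replicate 1 and 92.3 in replicate 2, and a summit 12968 bp from Abcb11, the bile salt export pump, scored 79.3 and 76.5. Beside Afp, which encodes the fetal plasma protein alpha-fetoprotein, a shared summit 2405 bp from the gene scored 28.5 in replicate 1 and 30.9 in replicate 2. The Alb and Abcb11 sites lie more than 10 kb from a gene end and were singled out after their values were seen.

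**Figure D1:**
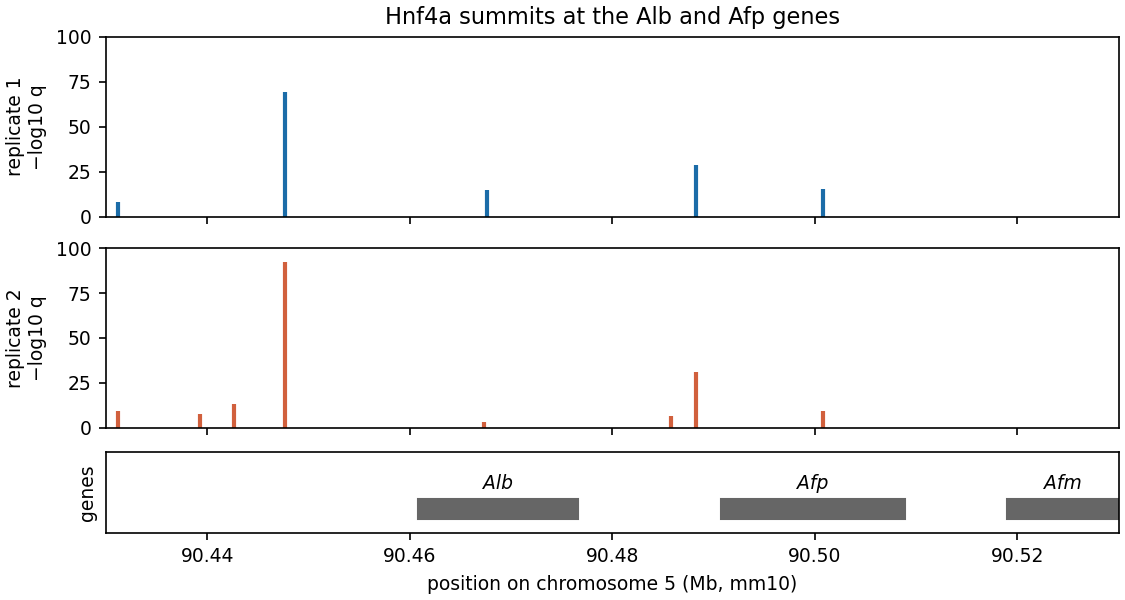
Hnf4a summits around Alb and Afp on chromosome 5 of mm10, with position in Mb on the x axis, the authors' −log10 q of each summit as the bar height in each replicate, and grey boxes for genes from start to end. The highest bar in both replicates, 69.5 and 92.3, stands 13149 bp outside Alb, and a summit of 28.5 and 30.9 stands beside Afp.

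Across the genome, 9193 summits of each replicate had a summit of the other within 100 bp. They made up 43.2% of replicate 1 (95% exact binomial interval 42.5 to 43.9) and 38.2% of replicate 2 (37.5 to 38.8). These shares describe a single overlap and differ only because the lists differ in length, so no spread between replicates is given. Placing the replicate 2 summits at random on their own chromosomes gave 0.261% and 0.231%, and random shifts of up to 100 kb gave 0.521% and 0.482%. In both cases the two-sided permutation p was 0.001 for both shares, the smallest that 1000 permutations can give. Both shares were tested on the same placements, so these are not separate tests. Merging both lists gave 36186 regions, of which 25.4% were shared. The share depended on the distance allowed: identical summit bases, the overlap rule planned first, made up 0.625% of replicate 1 and 0.552% of replicate 2, against 0.0104% and 0.00923% at random, with a permutation p of 0.001.

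Sharing rose with score. In the lowest score decile, 8.97% of replicate 1 summits and 2.24% of replicate 2 summits were shared, against 87.6% and 85.6% in the highest decile. Shared summits had median scores of 9.93 in replicate 1 and 9.61 in replicate 2, while the others had medians of 6.02 and 5.47. The best-scored summits without a counterpart lay in Runx2 (41.5) and Klhl6 (40.3) in replicate 1, and nearest to Col19a1 (48.4) and Adamts16 (42.1) in replicate 2. Each of these 4 stood between 115 and 232 bp from a summit of the other list. Of all summits, 43.9% in replicate 1 and 50.4% in replicate 2 had no counterpart within 500 bp.

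**Figure D2:**
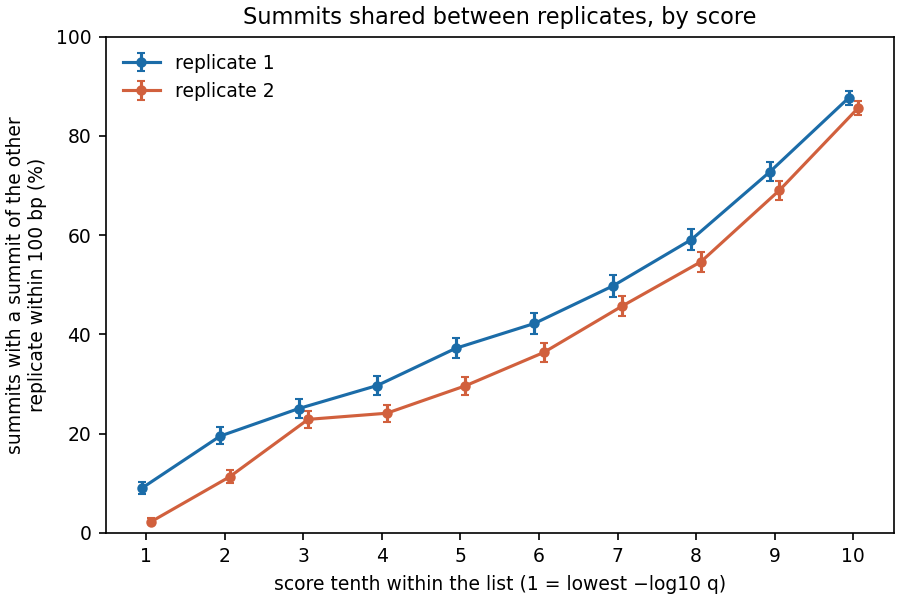
Percent of summits with a summit of the other replicate within 100 bp (y axis) by score decile of the list (x axis, lowest −log10 q first), with points for each replicate and bars for exact 95% binomial intervals. The share runs from 8.97% to 87.6% in replicate 1 and from 2.24% to 85.6% in replicate 2.

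The second comparison asked whether sites that scored high in replicate 1 also scored high in replicate 2. The highest-scored shared regions lay away from protein-coding genes. On chromosome 2, the summit at 98667132 scored 1799 in replicate 1 and 2028 in replicate 2, and the summit at 98662281 scored 1540 and 1856. They lay 1035460 and 1030609 bp from Lrrc4c, the nearest gene. The next on a chromosome was at 35305413 on chromosome 9, 29456 bp from Rpusd4, with 609 and 786. Among the other 7 of the top 10 by their worse rank, 2 were on unplaced scaffolds, and 5 lay on chromosomes 14, 8, 6, 9 and 16 at 22326 to 640371 bp from the nearest genes, Gm2244, Ankle1, Nxph1, Alkbh8 and B230307C23Rik. Of the regions ranked after these, those within 20 kb of a gene were singled out after their values were seen. They included regions inside Flt1, a receptor for vascular endothelial growth factor (120 and 131), and inside Antxr1, an anthrax toxin receptor (76.2 and 65.2). Another lay 11345 bp from Egln1, an oxygen-sensing prolyl hydroxylase (68.7 and 62.1). The Flt1 region and the top 10 were all among the 15 regions that scored over 100 in both replicates. High-copy sequence may account for those 15, as weighed below, though copy number was not measured. The widest shared regions, merged from neighbouring summits, spanned 146 bp beside Aph1a, which encodes a gamma-secretase subunit, and 100 bp near Pctp, which encodes a phosphatidylcholine transfer protein.

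Over the 9193 shared regions, Spearman's rho between the replicates' scores was 0.587 (95% bootstrap interval 0.572 to 0.600) and Pearson's r of the log10 scores was 0.666. These are correlations across regions, which are not independent replicates, so no p was computed. The median log2 ratio of the replicate 2 score over the replicate 1 score was −0.04.

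**Figure D3:**
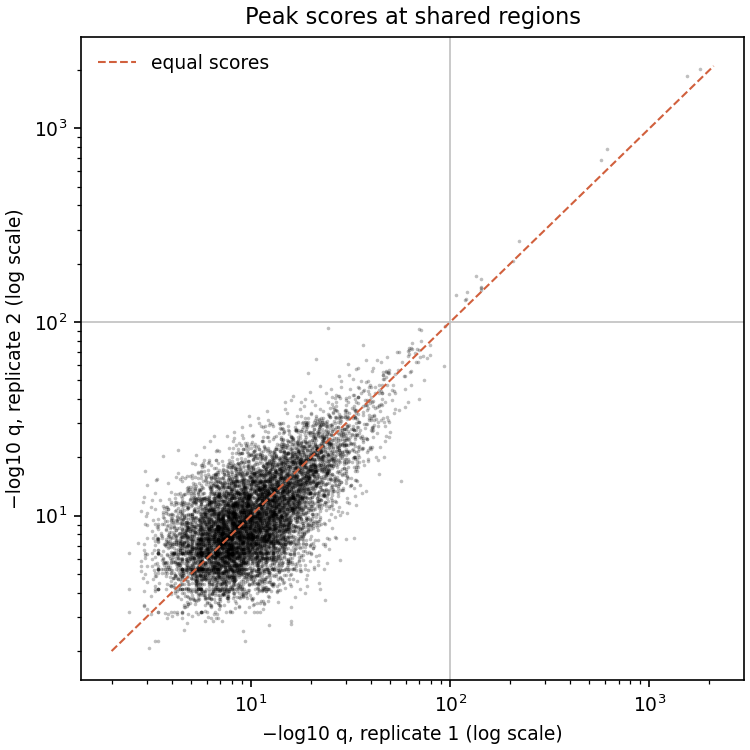
The authors' −log10 q at each of the 9193 shared regions in replicate 1 (x axis) and replicate 2 (y axis), both on log scales, with a dashed line for equal scores and grey lines at 100. Spearman's rho was 0.587, and 15 regions scored over 100 in both replicates.

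The third comparison asked where Hnf4a summits lie relative to genes. Shared regions were concentrated at the ends of protein-coding genes, where promoters and transcript ends lie. Examples at the very end of a gene were Rbp4, the plasma carrier of retinol, with a region 4 bp from a gene end (10.0 in replicate 1 and 10.7 in replicate 2), Kng1, the kininogen gene, at 7 bp (4.78 and 5.25), and Serpina1a, a plasma protease inhibitor, at 101 bp (10.9 and 4.30). These 3 genes were picked for their position after their values were seen. Of 9179 shared regions on chromosomes 1 to 19 and X, 18.5% (95% exact interval 17.7 to 19.3) lay within 1 kb of a gene end, 5.97 times the 3.10% of random positions. The lists taken alone gave 17.1% in replicate 1 and 15.1% in replicate 2, or 16.1% ± 1.40 (SD, n = 2). The two-sided Fisher's exact p was too small to be stored as a number in each of these 3 tests. This concentration was not particular to shared regions. Summits without a counterpart lay within 1 kb of a gene end in 16.1% of cases in replicate 1, 5.21 times the random share. In replicate 2 they did so in 13.1%, 4.20 times the random share. Random positions could fall where no reads can be placed.

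Gene interiors over 1 kb from both ends held 40.1% of shared regions against 39.0% of random positions (two-sided Fisher's exact p = 0.0524). The share was 41.3% in replicate 1 and 41.9% in replicate 2, against 39.4% and 39.0% at random (exact p = 3.2e-08 and 1.5e-18). Positions over 10 kb from any gene held 32.2% of shared regions against 49.3% of random positions (exact p = 4.8e-221). The gene table used has no strand, so promoters could not be told from transcript ends.

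**Figure D4:**
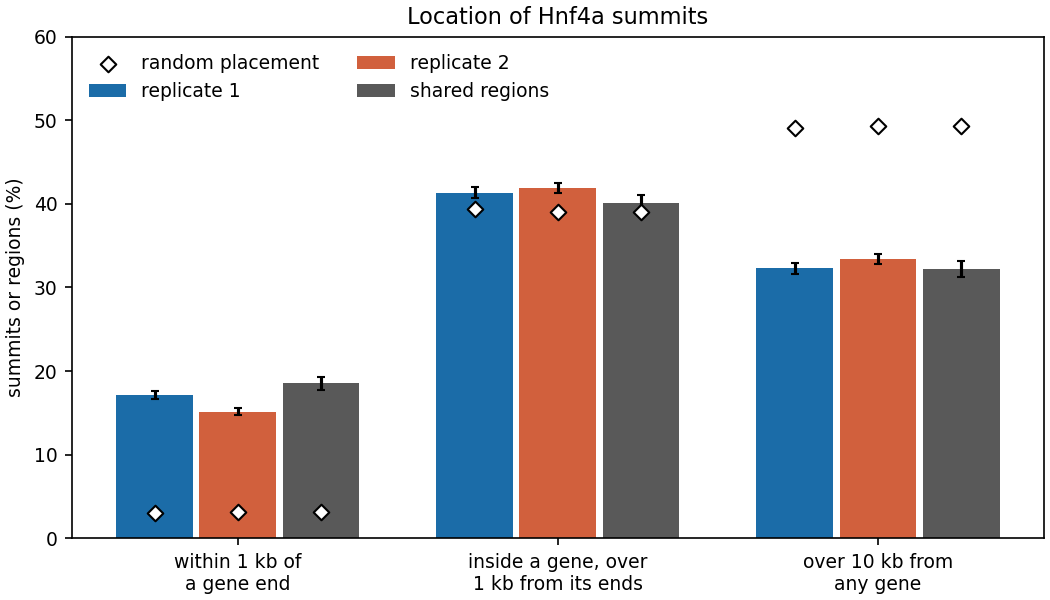
Percent of summits of each replicate and of shared regions (y axis) in 3 kinds of position (x axis), with bars for the observed share, error bars for exact 95% binomial intervals and white diamonds for random placement. Within 1 kb of a gene end the shares were 17.1%, 15.1% and 18.5% against about 3.10% at random.

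Chromosome X carried fewer summits per Mb than any autosome. It held 2.76 summits per Mb in replicate 1, 3.49 in replicate 2 and 0.893 shared regions per Mb. Chromosome 12, the lowest autosome in all 3 measures, held 7.46, 8.54 and 3.27 per Mb, although its density of protein-coding genes (5.83 per Mb) was close to that of X (5.87 per Mb). The autosomal medians were 8.72, 9.80 and 3.85 per Mb. Cldn2, a claudin of leaky epithelia, was a list gene on X with a shared region, 1544 bp from the gene (8.76 in replicate 1 and 7.82 in replicate 2). No test was run on these densities.

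The fourth comparison asked which groups of genes had shared Hnf4a regions within 10 kb of a gene end. Genes for plasma proteins, the main secreted products of hepatocytes, had such a region in 12 of 28 cases (42.9%), and genes of the p53 pathway and cell-cycle control in 8 of 16 (50%), while 4500 of all 21887 protein-coding genes did (20.6%). Olfactory receptor genes, which are silent in most cells outside the olfactory epithelium, had one in 10 of 1106 (0.904%). How well reads can be placed among such similar genes was not examined, so this low share may not reflect binding. By two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 15 lists, the odds ratio was 2.90 (95% interval 1.25 to 6.54, adjusted p = 0.0415) for plasma proteins, 3.87 (1.26 to 11.8, adjusted p = 0.0415) for the p53 list and 0.0331 (0.0158 to 0.0612, adjusted p = 5.9e-95) for olfactory receptors. Neither of the higher shares was robust: with olfactory receptors left out of the background and of the lists tested, the odds ratios were 2.73 and 3.63 and the adjusted p was 0.0792 for both, a setting that also takes a passing list out of the adjustment, and of 11 alternatives the plasma protein list passed in 2 and the p53 list in 5. By the same exact test, the odds ratio of the plasma proteins was 4.62 (adjusted p = 0.00118) with replicate 1 alone and 2.93 (adjusted p = 0.0505) with replicate 2 alone, and that of the p53 list was 3.38 (adjusted p = 0.0845) with replicate 1 alone and 3.05 (adjusted p = 0.152) with replicate 2 alone.

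**Figure D5:**
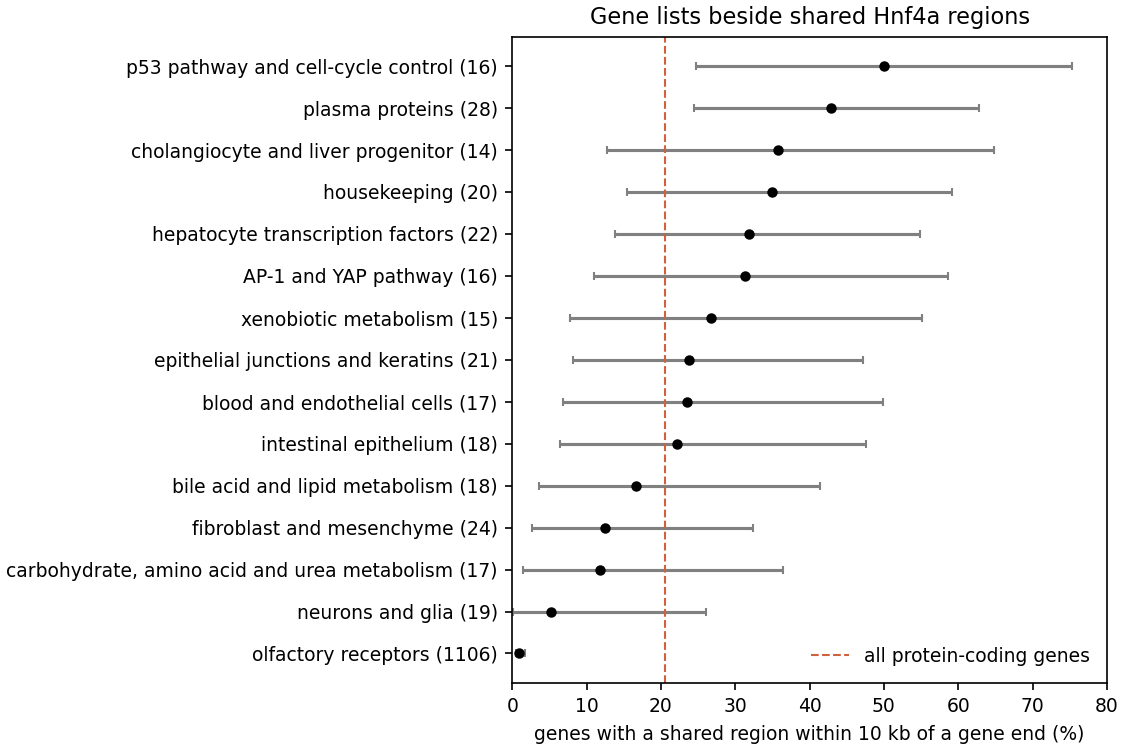
Percent of each list's genes with a shared region within 10 kb of a gene end (x axis) for 15 gene lists (y axis, number of genes in brackets), with bars for exact 95% binomial intervals and a dashed line at the 20.6% of all protein-coding genes. The p53 list (50%) and plasma proteins (42.9%) lie highest and olfactory receptors (0.904%) lowest.

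Among plasma protein genes, Afp had the best-ranked region. Fgg and Fga, which encode chains of fibrinogen, lie on either side of 1 shared region at 83020637 to 83020663 on chromosome 3, which scored 28.8 in replicate 1 and 17.3 in replicate 2, and Fgb, which encodes the remaining chain, had a region 5534 bp from its nearer end (19.1 and 8.96). Apoh, a phospholipid-binding plasma protein, had a region inside the gene (16.6 and 21.4). The other members with a shared region were Apoa2, Rbp4, Serpind1, Serpinc1, Trf, Serpina1a and Kng1. Of the p53 list, Mdm2, the ubiquitin ligase that degrades p53, had a region inside the gene 571 bp from its end (13.1 and 12.7), Cdkn1a, an inhibitor of cyclin-dependent kinases, had a region inside the gene (8.99 and 28.6), Sesn2, a stress-induced regulator of growth signalling, had a region 5272 bp away (11.7 and 17.8), and Cdkn1b, a further kinase inhibitor, had a region 3088 bp away (9.50 and 7.64). Trp53 itself, Ccng1, Cdkn2a and Btg2 were the remaining 4.

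The other liver lists did not pass the test. Of hepatocyte transcription factors, 7 of 22 had a shared region (31.8%, adjusted exact p = 0.408), among them Nr1h4, the bile acid receptor (16.0 in replicate 1 and 14.998 in replicate 2), Nr1i2 (15.2 and 13.2) and Nr1i3 (13.8 and 14.4), which sense foreign compounds, and Cebpa (12.6 and 10.8), which drives hepatocyte differentiation. The Nr1i3 region is also that of its neighbour Apoa2. Bile acid and lipid metabolism had 3 of 18 (adjusted exact p = 1), among them Cyp8b1, an enzyme of cholic acid synthesis (14.8 and 18.6), and Baat, which conjugates bile acids (13.4 and 15.9). Carbohydrate, amino acid and urea metabolism had 2 of 17 (adjusted exact p = 0.751), the liver pyruvate kinase gene Pklr (10.5 and 4.70) and the tyrosine aminotransferase gene Tat (11.7 and 4.23). Xenobiotic metabolism had 4 of 15 (adjusted exact p = 0.751), with Cyp1a2 (25.4 and 20.6) and Cyp2b10 (13.3 and 8.68), which oxidise drugs, the sulfotransferase gene Sult1a1 (14.8 and 11.5) and the glutathione transferase gene Gstm1 (7.90 and 5.87). Pooled, these 4 lists and plasma proteins held 100 genes, of which 28% had a shared region against 20.5% of all other genes (odds ratio 1.51, 95% interval 0.935 to 2.36, two-sided Fisher's exact p = 0.0812, adjusted over 6 tests 0.0975). The share was 52% against 39.4% of other genes in replicate 1 alone (odds ratio 1.67, 95% interval 1.10 to 2.53, exact p = 0.0134, adjusted 0.0653) and 53% against 41.9% in replicate 2 alone (odds ratio 1.56, 1.04 to 2.37, exact p = 0.0257, adjusted 0.0653). Without olfactory receptors among the other genes, the adjusted exact p was 0.143 for shared regions, 0.0653 for replicate 1 and 0.0975 for replicate 2. These pooled tests were chosen after the list results were seen.

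Lists of other cell types and general functions did not pass either. Epithelial junctions and keratins had 5 of 21 (adjusted exact p = 0.842), including the tight junction genes F11r (15.6 in replicate 1 and 12.3 in replicate 2) and Cldn1 (11.2 and 15.3), and passed only when regions up to 50 kb from a gene end were counted (17 of 21, adjusted exact p = 0.00889). Cholangiocyte and progenitor genes had 5 of 14 (adjusted exact p = 0.408), among them Krt19, a keratin of bile ducts (7.93 and 13.1), and intestinal epithelium had 4 of 18 (adjusted exact p = 0.842), among them Fabp2, a fatty acid carrier of enterocytes (22.7 and 11.4), and the intestinal regulator Cdx2 (12.8 and 8.08). The AP-1 and YAP pathway had 5 of 16 (adjusted exact p = 0.653), including the receptor kinase gene Axl (26.4 and 28.1) and Ajuba (18.7 and 32.0), which acts in Hippo signalling. Housekeeping genes had 7 of 20 (adjusted exact p = 0.408), among them Ywhaz, which encodes a phosphoserine-binding adaptor protein (16.1 and 22.4). Blood and endothelial cells had 4 of 17 (adjusted exact p = 0.842), including Cd4 (11.99 and 12.8), and neurons and glia had 1 of 19 (adjusted exact p = 0.408), Neurod1 (9.42 and 8.67). Of the 10 olfactory receptor genes, Olfr1124 (24.5 and 27.1) and Olfr183 (18.2 and 21.7) had the best-ranked regions.

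Fibroblast and mesenchyme genes, which mark the cells that were reprogrammed, had shared regions in 3 of 24 cases (12.5%, adjusted exact p = 0.751). These were Zeb1 (12.3 in replicate 1 and 11.9 in replicate 2) and Zeb2 (11.4 and 11.4), repressors of epithelial genes, and S100a4 (5.22 and 5.77). Taken alone, replicate 1 had a summit within 10 kb of 5 of the 24 and replicate 2 of 14, and 2 genes were found in replicate 1 only against 11 in replicate 2 only. The two-sided exact McNemar p was 0.0225, and 0.168 after adjustment over the 15 lists. Best scores beside the 11 genes found in replicate 2 only ran from 3.04 to 10.1, mostly below that list's median of 6.67. Comparisons of the pooled liver genes with single lists were chosen after the list results were seen. In replicate 1, the pooled liver genes had summits more often (52%) than the fibroblast genes (20.8%, two-sided Fisher's exact p = 0.0064, adjusted over 12 tests 0.0384), while in replicate 2 the shares were 53% and 58.3% (exact p = 0.657, adjusted 0.788). For shared regions they were 28% and 12.5% (exact p = 0.188, adjusted 0.450). Genes of neurons and glia had summits less often than the pooled liver genes in replicate 1 (15.8%, exact test, adjusted p = 0.0384) and in replicate 2 (21.1%, adjusted p = 0.0495), but the difference did not pass for shared regions (5.26%, adjusted p = 0.121). Blood and endothelial genes had 35.3% in replicate 1, 41.2% in replicate 2 and 23.5% for shared regions, and the difference from the liver genes did not pass the exact test (adjusted p = 0.571, 0.655 and 1). Housekeeping genes had 65%, 50% and 35%, and that difference did not pass the exact test either (adjusted p = 0.571, 0.886 and 0.788).

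At the genes of both introduced factors, summits were listed inside Hnf4a in replicate 1 and at neither gene in replicate 2, a difference that was not tested. Hnf4a, at 163506811 to 163572907 on chromosome 2, held 4 summits in replicate 1, at 163514342, 163515778, 163530796 and 163540760, with scores of 12.4, 7.38, 3.43 and 6.08. Reads from the retroviral Hnf4a sequence would align to exons of this gene. Exon positions were not available here, so such reads cannot be told apart from Hnf4a binding. Replicate 2 had none inside Hnf4a or within 10 kb of it, and its nearest summit was 12389 bp from a gene end. Foxa2, which encodes a pioneer factor of endoderm, had no summit within 10 kb in either replicate, the nearest being 75474 bp away in replicate 1 and 86265 bp away in replicate 2. A missing summit means only that none was listed, since the lists leave out all positions below the authors' threshold.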

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

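Both tests in this part were chosen only after the result was seen. Summits on unplaced or unlocalised scaffolds, which the comparisons with genes did not use, numbered 18 in replicate 1 and 21 in replicate 2, and 13 shared regions lay there. They are given as values only: with no control samples there is no expected number to set them against.

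The pattern weighed was that the highest-scored shared regions lay far from genes. Of the 15 regions that scored over 100 in both replicates, 8.33% of the 12 on placed chromosomes (1 region, inside Flt1) lay inside or within 10 kb of a gene, against 67.9% of the other shared regions (two-sided Fisher's exact p = 3.2e-05). This share is the pattern itself, so Hnf4a binding cannot be told apart by it and stays open as a source. Unplaced scaffolds held 20% of the 15 against 0.109% of the others (exact p = 9.96e-07), so high-copy sequence, whose reads pile up where the assembly holds few copies, may account for them. This stays a hypothesis, since copy number was not measured and the sequence was not used here. No biological explanation from the design was tested, because there is 1 group.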

How the results depend on the processing

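The alternatives that changed the sharing distance to 50, 200 or 500 bp, left out regions over 100, counted gene interiors, adjusted for gene length and density, left out olfactory receptors or kept 1 member per neighbouring group were chosen only after the data were seen. Of 211 values under alternatives, 184 were counted as unchanged, 15 lost a call, 11 moved and 1 gained a call. Unchanged meant the same side of the threshold or, for rho, a value inside its bootstrap interval. Many of the 184 came from the 12 lists without a call, which passed only for epithelial junctions and keratins at 50 kb. The 184 therefore say little about both lists with higher shares, which passed in 2 (plasma proteins) and 5 (p53 list) of 11 alternatives. Counts had a wide tolerance. The number of lists with more members also counted as unchanged at 50 kb (2). There, epithelial junctions and keratins took the place of plasma proteins. With −log10 q of 5 or more, summits fell from 21283 to 16668 in replicate 1 and from 24097 to 17467 in replicate 2, and both were counted as unchanged. No called result reversed, but 22 of the 184 were list results that changed direction without a call in either setting. The excess of shared summits over random placement and of shared regions at gene ends held under each alternative run, with shares at gene ends of 15.1% to 17.1% for each replicate alone, and fewer olfactory receptor genes had regions in 10 of 10 alternatives. Spearman's rho was 0.565 for the top 10000 summits and 0.570 at 200 bp. The number of lists with more members, 2 in the report, was 0 with a 1 kb window, with −log10 q of 5 or more, with gene interiors and without olfactory receptors, 1 at 50 bp, 1 at 200 bp and 1 with 1 member per group, and 0 to 1 with either replicate left out. The odds ratio of plasma proteins, without a call, was 1.25 at 1 kb, 2.40 at 50 kb, 2.14 at −log10 q of 5 or more, 1.86 at 50 bp, 2.75 at 200 bp, 2.13 with gene interiors, 2.73 without olfactory receptors and 2.49 with 1 member per group, and, with either replicate left out, it ran from 2.93 (no call, without replicate 1) to 4.62 (called, without replicate 2); its adjusted p ranged from 0.00118 to 0.915. That of the p53 list, without a call, was 1.49 at 1 kb, 3.51 at −log10 q of 5 or more, 3.66 with gene interiors and 3.63 without olfactory receptors, and 3.05 to 3.38 with either replicate left out; its adjusted p ranged from 0.00889 to 0.915. Fewer regions remain under the stricter score and the narrower windows; otherwise the cause was not tested. Motif alternatives, those without the widest peaks, fold enrichment and the CpG covariate were not run. No paired analysis was possible because there is 1 group. With 14 to 28 genes in most lists, only large differences could pass, and unknown read depth leaves open how many sites each library could have listed.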

Other observations

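In this part, the families of gene symbols, the counts of regions per gene and the tests on weak summits and housekeeping genes were chosen only after the result was seen. The tests of the p53 list with covariates and of further p53 targets were chosen after that list's result was seen, but before their own. Genes whose interior held the most shared regions were Rad51b, a gene of homologous recombination, with 15 over 551 kb, and Stard13, with 10 over 391 kb. Per length, the genes with 5 or more were led by Rasgef1b, a guanine nucleotide exchange factor, with 5 over 35.5 kb (14.1 per 100 kb), Cab39, a partner of the kinase Stk11, with 5 over 58.1 kb (8.60 per 100 kb), and Abhd2, a lipase, with 5 over 88.3 kb (5.66 per 100 kb). Such counts depend on gene length and were not tested.

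Of 112 symbol families with 20 or more genes, 14 differed from other genes in how often a shared region lay within 10 kb of a gene end (two-sided Fisher's exact test, adjusted), 5 with more and 9 with fewer. Neighbouring members are not independent, and with 1 member kept per group within 100 kb, 5 of the 14 still passed. Sec genes of vesicle transport and protein translocation (14 of 29, odds ratio 3.61) and Ppp genes of protein phosphatase subunits (28 of 77, odds ratio 2.22) had more, with exact adjusted p of 0.013 and 0.0221 over all members and 0.0277 and 0.0266 with 1 per group. Vmn genes of vomeronasal receptors (7 of 355, odds ratio 0.0763) and genes known only by a Gm number, mostly predicted gene models (84 of 1329, odds ratio 0.247), had fewer, with exact adjusted p of 1.1e-24 and 2.4e-48 over all members and 0.000249 and 1.5e-23 with 1 per group, as had olfactory receptors. The other 9 passed only with all members: Gtf, Cdc and Tmem genes had more and Scgb, Pramel, Rhox, Defa, Tas and Klk genes fewer, with exact adjusted p from 0.00625 to 0.0439 over all members and from 0.0932 to 1 with 1 per group. For Gtf, Cdc and Tmem genes the odds ratio changed little, from 3.55, 3.01 and 1.52 to 3.52, 2.80 and 1.48. Their lost calls thus do not show that neighbouring members carried the difference. Scgb and Pramel genes had no region with 1 per group, and the odds ratio of Tas genes moved from 0.104 to 0.351. Rhox, Defa and Klk genes kept only 3, 1 and 1 groups. All 33 Rhox genes lie on chromosome X, which had the lowest density of shared regions. For the families with fewer regions, how well reads can be placed among similar genes was not examined.

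Weak summits of replicate 2 were seldom shared (2.24% in its lowest score decile). Background summits placed evenly along the chromosomes may add to them but are argued against as the whole source. Of the unshared ones, 4.50% (95% exact interval 3.70 to 5.42) lay within 1 kb of a gene end, against 3.15% of random positions. The random positions matched all replicate 2 summits, not only the weak ones, and could fall where no reads can be placed. Background limited to sequence where reads can be placed therefore stays open. A lower depth of replicate 2 cannot be told apart, because its scores at shared regions were slightly lower (median log2 ratio −0.0434) while its list was longer, and read depth is unknown. No biological explanation was tested.

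The p53 list had shared regions beside 8 of its 16 genes. Gene density and gene length are argued against as the source, because with both as covariates the odds ratio was 4.92 (95% interval 1.80 to 13.4). Promoters open in most cells stay open as an explanation: housekeeping genes had 35%, below the 50% of the p53 list but not separable from it (two-sided Fisher's exact p = 0.500). The hypothesis that p53 target genes as a class lie near Hnf4a sites was tested on 31 further targets, of which 11 had a region, among them Perp, Sesn1, Ddit4 and Gdf15, which were picked after their values were seen. Their odds ratio was 2.13 (two-sided Fisher's exact p = 0.0464), as the hypothesis predicts, but its 95% interval of 0.920 to 4.66 includes 1. The share of these further targets, 35.5%, was close to the 35% of housekeeping genes. It therefore cannot separate the hypothesis from promoters open in most cells. Olfactory receptors were kept among the other genes, and the test was not repeated without them.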
